A study of Mus musculus with 12 samples.

How the data were processed

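The series holds 12 Affymetrix arrays of total RNA from mouse small intestine, with 6 arrays from mice on a control high-fat diet and 6 from mice on a diet low in the ratio of polyunsaturated to saturated fatty acids. Per the labels, the animals were male FVB mice with an age of 8 weeks, the diets were given for 8 weeks, and 500 ng of total RNA was labelled by the whole-transcript sense target method without removal of ribosomal RNA. The part of the small intestine, the time of dissection, feeding before dissection, scan dates and batches are not given in the labels.

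The deposited values are array intensity values on a linear scale, 1 per probe set and array. How the authors summarized and normalized them is not given in the sources used here. The table held 34760 probe sets with values between 17.7 and 20294, so a constant may have been added or a background kept. The unknown scaling limits the reading of small differences shared by many genes, and the number of arrays limits the precision of every value. The median standard error of the log2 difference was 0.061.

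Of the probe sets, 21640 named 1 gene symbol, 1321 named several and 11799 named none. Symbols were checked through Entrez gene IDs, of which 21553 matched, and 0 symbols were updated. Probe sets naming exactly 1 gene were used, and for the 954 genes with more than 1 such probe set the brightest by its mean over all 12 arrays was taken, which left 19937 genes. The log2 of the deposited value was used. Genes below the 40th percentile of mean level (a geometric mean intensity of 85.6) were left out as dim before adjustment, which removed 7975 genes and left 11962. No genome coordinates were used.

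The diets were compared per gene with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with diet as the only term, and p-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. The arrays share replicate numbers between diets. The numbers were not treated as pairs, and a fit with the number as a replicate block was run as an alternative.

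Before the data were examined, 38 gene lists with 583 symbols were fixed, of which 533 were found. They covered cholesterol synthesis, sterol sensing and uptake of low-density lipoprotein, cholesterol transport, targets of the liver X receptor, fatty acid oxidation and targets of peroxisome proliferator-activated receptor alpha, fatty acid uptake to chylomicrons, fatty acid synthesis, desaturation and elongation, bile acid transport, proximal and distal segment markers, carbohydrate and peptide digestion, retinoid and xenobiotic metabolism, oxidative stress, the unfolded protein response, interferon response, class II antigen presentation, inflammation, Paneth, goblet, enteroendocrine, tuft and crypt stem cells, proliferation, smooth muscle, enteric neurons and glia, adipose tissue, exocrine pancreas, B and plasma cells, T cells, macrophages and dendritic cells, mast cells, endothelium, fibroblasts, erythrocytes, the circadian clock, immediate early genes and the respiratory chain. Of 447 tested symbols, 28 stood in more than 1 list. The 35 lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Fry, which tests whether a list moves on balance in 1 direction, and camera with an estimated correlation were run beside it. The score of a list per array was the mean log2 value of its tested members, and scores were compared by exact two-sided permutation tests over all arrangements of the 12 arrays, with 95% intervals from inverting the test. These used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3, and plots used matplotlib 3.10.9.

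The genes named were chosen by a rule fixed before the data were examined. It took the 12 largest passing differences in each direction, passing over unnamed loci, receptor families and immunoglobulin segments, then up to 4 members of smallest p in each list, and 20 genes of sterol and fatty acid handling whatever their values. This gave 160 analysed genes. Other genes are named as chosen after their values were seen. Some of the genes fixed by the rule or the lists were not analysed here.

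The steps were tested on simulated data with 11962 genes and 6 arrays per group. Of 50 genes planted at each size, 31 were recovered at a log2 difference of 0.25, 49 at 0.5, 49 at 1 and 50 at 2, and 10 of 201 calls (4.98%) were false. A planted list with a shift of 0.25 was called and 0 of 34 others were. The genes were simulated independently of each other, so false calls of lists whose members move together were not checked. The exact 95% interval covered the planted difference in 189 of 200 simulations.

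Alternatives fixed before the data were examined were quantile normalization, median centring, no filter and a filter at the 60th percentile, the mean of probe sets, array weights, a trended robust prior, the replicate block, a pseudocount of 16, an ordinary variance per gene, an estimated correlation, fry and each array left out in turn. A pseudocount of 1, subtraction of 16 and leaving out control arrays 1 and 2 together were chosen after seeing the data. Other splits of the 12 arrays were counted in 100 drawn of 462. Probe sets naming several genes or none were left out of the gene comparison and are described among the closing observations.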

Results

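Gene expression was measured with Affymetrix whole-transcript arrays in the small intestine of 12 male FVB mice. For 8 weeks, 6 mice received a control high-fat diet and 6 received a diet with a low ratio of polyunsaturated to saturated fatty acids (low P/S diet). The design text calls the 6 arrays of each group biological replicates, and p-values refer to these animals. The median intensity per array lay between 91.9 and 99.5, and 11962 genes were bright enough to be tested. Differences are low P/S minus control on the log2 scale, ± is the standard error from limma, intensities are geometric means over 6 arrays, and each p named as adjusted is a Benjamini-Hochberg value.

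The comparison of the 2 diets addressed how a more saturated dietary fat alters the intestine, which the series title ties to the excretion of cholesterol through the intestinal wall. On the low P/S diet the intestine had more transcript of the desaturase genes Scd1, Scd2, Fads1 and Fads2 and of all 17 measured cholesterol synthesis genes. The same held for 25 of 32 genes of fatty acid oxidation and targets of peroxisome proliferator-activated receptor alpha. In these lists the intestine had no passing gene with less transcript on that diet. It had less transcript of 13 of 16 carbohydrate and peptide digestion and absorption genes, of the cholesterol uptake protein gene Npc1l1, of the circadian output genes Dbp and Tef and of 7 of 9 class II antigen presentation genes. No gene list passed camera with an estimated correlation (smallest adjusted p = 0.247). Times of dissection and of last feeding are not given, and the clock genes differed between the diets. An effect of such times on any of these genes was not separated from that of the diet. In total 3074 genes (25.7% of those tested) passed at an adjusted p under 0.05, of which 2132 were higher and 942 lower on the low P/S diet. A list whose share of passing genes lies near 25.7% therefore does not stand out from the other genes. Quantile normalization gave 1773 higher and 1543 lower, so the balance of directions depended on the scaling. Differences over 2-fold were few, with 24 genes higher and 33 lower.

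**Figure D1:**
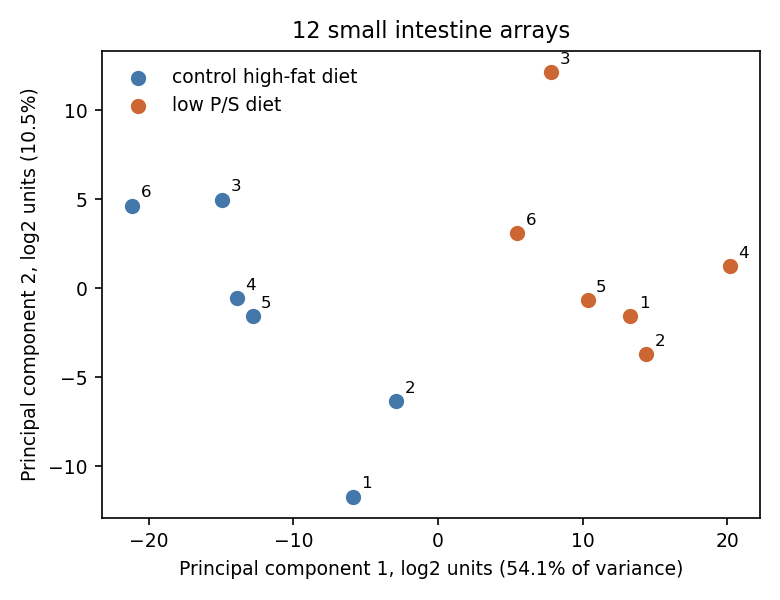
Principal components of the 12 arrays from the log2 intensities of the tested genes, in log2 units, with 54.1% of the variance on the horizontal and 10.5% on the vertical axis; each point is 1 array with its replicate number. The control arrays lie between -21.1 and -2.90 on the first component and the low P/S arrays between 5.48 and 20.2, with control arrays 1 and 2 nearest to the low P/S group.

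The groups separated in all 6 arrays of each diet for 1287 genes (10.8% of those tested), against 0.216% by chance. Control arrays 1 and 2 lay nearest to the low P/S group, and without both of them 3852 genes passed, 2718 higher and 1134 lower.

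Scd2 (probe set 10463355), a stearoyl-CoA desaturase that puts the first double bond into saturated fatty acids, rose most, by 3.88 ± 0.18 or 14.8-fold, from an intensity of 264 to 3905 (adjusted p = 4.13e-09). Its relative Scd1 rose 5.44-fold to an intensity of 10582, and Fads2, a desaturase of polyunsaturated fatty acid synthesis, rose 2.55-fold. Trf, which encodes the iron carrier transferrin, rose 7.16-fold (2.84 ± 0.19, adjusted p = 2.43e-07). The 12 largest rises also included the acyl-CoA thioesterase gene Acot1 (4.55-fold), the class I histocompatibility gene H2-Q10 (3.06-fold), the secreted lectin gene Reg4 (2.92-fold) and the glycerol-3-phosphate acyltransferase gene Gpam (2.83-fold). The others were Insig1, whose protein holds back the activation of sterol regulatory factors (2.76-fold), the nuclear receptor gene Nr0b2 (2.64-fold), the lipid droplet coat gene Plin2 (2.60-fold) and the phosphatase gene Dusp14 (2.59-fold). Probe sets were assigned by gene symbol, and hybridization shared between close paralogs such as Scd1 and Scd2, or Acot1 and Acot2, was not tested.

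Enpp7 (probe set 10383047), the alkaline sphingomyelinase of the brush border, fell most, from an intensity of 3040 to 456, or 6.67-fold (-2.74 ± 0.15, adjusted p = 2.13e-08). Ly6m was 5.36-fold lower, and Cubn, which encodes the cobalamin uptake receptor cubilin, was 4.56-fold lower. The clock output gene Dbp was 4.10-fold lower. Transporter genes made up 5 of the 12 largest falls: Slc13a2 for dicarboxylates (4.04-fold lower), Slc13a1 for sulphate (3.56-fold), Slc23a4 for nucleobases (3.16-fold), Slc7a15 of an amino acid transporter family (3.02-fold) and Slc15a1 for dietary peptides (2.98-fold). Tns4 was 3.69-fold lower, the adenosine deaminase gene Ada 2.86-fold lower and Pmp22 2.77-fold lower. In all 24 of these genes every low P/S array lay beyond every control array.

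**Figure D2:**
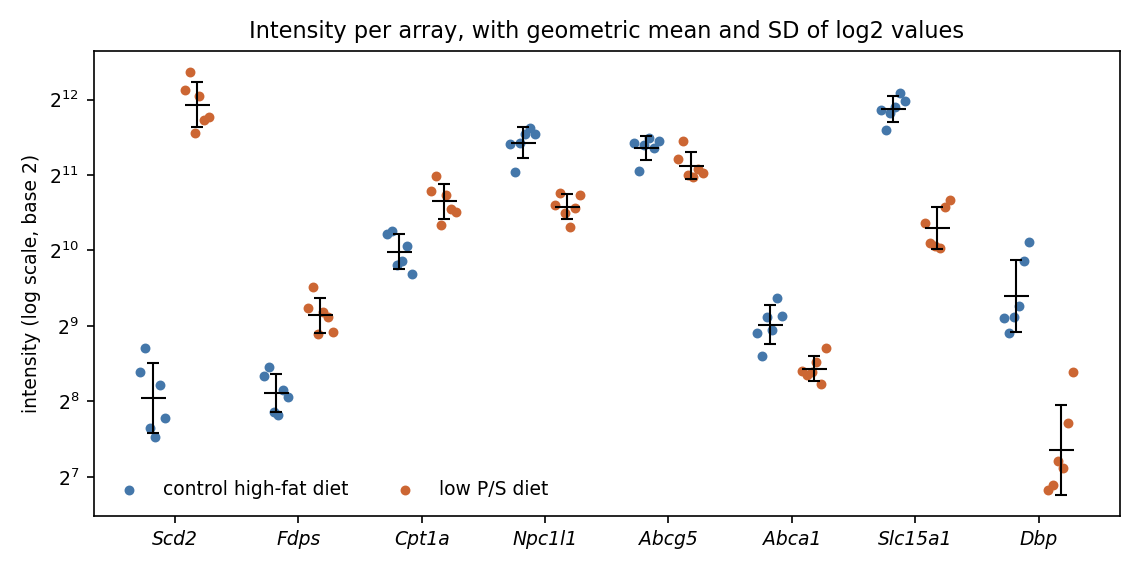
Intensity of 8 genes in each of the 6 control and 6 low P/S arrays (points, log axis to base 2), with the geometric mean and the SD of the log2 values as bars. Every low P/S array lies beyond every control array for Scd2, Fdps, Cpt1a, Npc1l1, Slc15a1 and Dbp, whereas the diets overlap for Abcg5 and Abca1.

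All 17 measured genes of cholesterol synthesis rose, both over all genes tested and adjusted over the list alone, with a median difference of 0.71. Fdps, which makes farnesyl pyrophosphate, rose 2.03-fold (1.02 ± 0.12), Nsdhl 1.89-fold (0.92 ± 0.10), Tm7sf2 1.76-fold (0.81 ± 0.09) and the squalene synthase gene Fdft1 1.64-fold (0.71 ± 0.08). The list passed camera (adjusted p = 5.46e-13) but not with an estimated correlation (adjusted p = 0.293 with an estimated correlation), and its mean difference of 0.70 had an exact 95% interval of 0.48 to 0.92 (exact permutation p = 0.0022, the smallest that 6 against 6 arrays can give). Srebf2, the transcriptional regulator of this pathway, rose 1.27-fold (0.35 ± 0.07, adjusted p = 0.00162).

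Among 14 genes of sterol sensing and uptake of low-density lipoprotein, 4 rose, 3 fell and 7 did not pass. Adjusted over the list alone, 4 rose and 4 fell. Insig1 and Srebf2 rose, while Npc1, which exports cholesterol from lysosomes, and the lipoprotein receptor gene Lrp1 fell by 0.39 and 0.32 on the log2 scale, of which Lrp1 did not pass with an ordinary variance per gene (adjusted p = 0.0615). The list did not pass camera (adjusted p = 0.682), and quantile normalization gave 2 higher and 5 lower.

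Of 14 genes of cholesterol transport, 2 rose, 3 fell and 9 did not pass, and adjusted over the list alone 3 rose and 7 fell. Npc1l1, the apical protein through which enterocytes take up cholesterol, was 1.80-fold lower, at an intensity of 1528 against 2756 (fell by 0.85 on the log2 scale, SE 0.09, adjusted p = 1.88e-05). Abca1, which exports cholesterol to high-density lipoprotein, was 1.5-fold lower (adjusted p = 0.00104), and the multidrug transporter gene Abcb1a was 1.49-fold lower (adjusted p = 0.00404). Apoe rose 1.35-fold. The lipoprotein receptor gene Scarb1 rose 1.12-fold (adjusted p = 0.0284), a call that ended without control array 2 or 4 or low P/S array 2 or 6, with a highest adjusted p of 0.0695.

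Abcg5 and Abcg8, which together form the apical exporter of sterols into the gut lumen, did not pass, with differences of -0.24 ± 0.09 (adjusted p = 0.0530) and -0.27 ± 0.11 (adjusted p = 0.0857). Control array 2 was the lowest control array for Abcg5. Without it the differences were -0.30 for Abcg5 (adjusted p = 0.00947) and -0.33 for Abcg8 (adjusted p = 0.0380), and without low P/S array 2 they were -0.30 (adjusted p = 0.00971) and -0.35 (adjusted p = 0.0219). With quantile normalization both passed as lower (-0.32, adjusted p = 0.0180, and -0.37, adjusted p = 0.0240), and Abcg5 also did so with the 60th percentile filter (adjusted p = 0.0454) and with array weights (adjusted p = 0.0492). Neither gene had a positive difference in these fits. Abcb1b was too dim to test, at intensities of 72.0 on the control and 62.8 on the low P/S diet, and Soat2 was not analysed here. The cholesterol transport list passed camera as lower (adjusted p = 0.0226; adjusted p = 0.347 with an estimated correlation), and this call ended without control array 5 (adjusted p = 0.0529) or low P/S array 5 (adjusted p = 0.0613). Quantile normalization gave 2 higher and 7 lower members.

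Of 14 targets of the liver X receptor, a sterol-activated nuclear receptor, 7 rose, 1 fell and 6 did not pass, and adjusted over the list alone 7 rose and 4 fell. The rises were led by Scd2 and Scd1 and included Lpcat3, a phospholipid remodelling gene (1.31-fold), while Abca1 fell. The list did not pass camera (adjusted p = 0.324), and its median difference was 0.13. Fry called it (adjusted p = 0.00298) and its mean difference was 0.48 (exact 95% interval 0.33 to 0.62, exact permutation p = 0.0022), but without Scd1 and Scd2, a choice made after seeing the data, the mean of the other 12 was 0.03 (exact 95% interval -0.08 to 0.13, exact permutation p = 0.574). Its count of lower members was 5 with quantile normalization and 3 without control arrays 1 and 2.

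Fatty acid genes rose in 3 lists. In fatty acid oxidation and targets of peroxisome proliferator-activated receptor alpha, 25 of 32 genes rose and 7 did not pass, and 27 rose adjusted over the list alone (median 0.41). Acot2 rose 2.52-fold (1.33 ± 0.16), the peroxisomal oxidation gene Ehhadh 1.88-fold (0.91 ± 0.11), the enoyl-CoA isomerase gene Eci1 1.49-fold (0.58 ± 0.07), and Cpt1a, which controls fatty acid entry into mitochondria, 1.59-fold (0.67 ± 0.11). The list passed camera (adjusted p = 5.46e-13; adjusted p = 0.316 with an estimated correlation).

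In fatty acid synthesis 12 of 15 genes rose and 3 did not pass, and 13 rose adjusted over the list alone (median 0.69). Me1, a malic enzyme that supplies NADPH, rose 2.25-fold (1.17 ± 0.13), the acetyl-CoA carboxylase gene Acacb 1.91-fold (0.94 ± 0.11) and the pentose phosphate gene Pgd 1.74-fold (0.80 ± 0.09). Camera called the list higher (adjusted p = 4.30e-08; adjusted p = 0.316 with an estimated correlation). Srebf1, a transcriptional regulator of lipid synthesis, rose 1.48-fold (0.56 ± 0.15, adjusted p = 0.0110), but did not pass with an ordinary variance per gene (adjusted p = 0.0520).

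In desaturation and elongation 9 of 13 genes rose and 4 did not pass, and 10 rose adjusted over the list alone (median 0.49). Besides Scd2 and Fads2, the desaturase gene Fads1 rose 1.47-fold (0.56 ± 0.06) and Tecr, of the elongation cycle, 1.41-fold (0.49 ± 0.06). As a group these genes passed camera (adjusted p = 2.40e-08; adjusted p = 0.255 with an estimated correlation).

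Genes of fatty acid uptake, triglyceride resynthesis and chylomicron assembly split, with 8 of 25 higher, 4 lower and 13 not passing. Adjusted over the list alone, 8 rose and 5 fell. Plin2 rose 2.60-fold, the acyltransferase gene Agpat2 1.65-fold and the lipid droplet gene Fitm2 1.32-fold, while the acyltransferase gene Gpat3 fell by 0.33 on the log2 scale. The fatty acid receptor gene Cd36 had a difference of -0.01 ± 0.06 (adjusted p = 0.924), whose sign turned with median centring to 0.02. The list did not pass camera (adjusted p = 0.621).

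**Figure D3:**
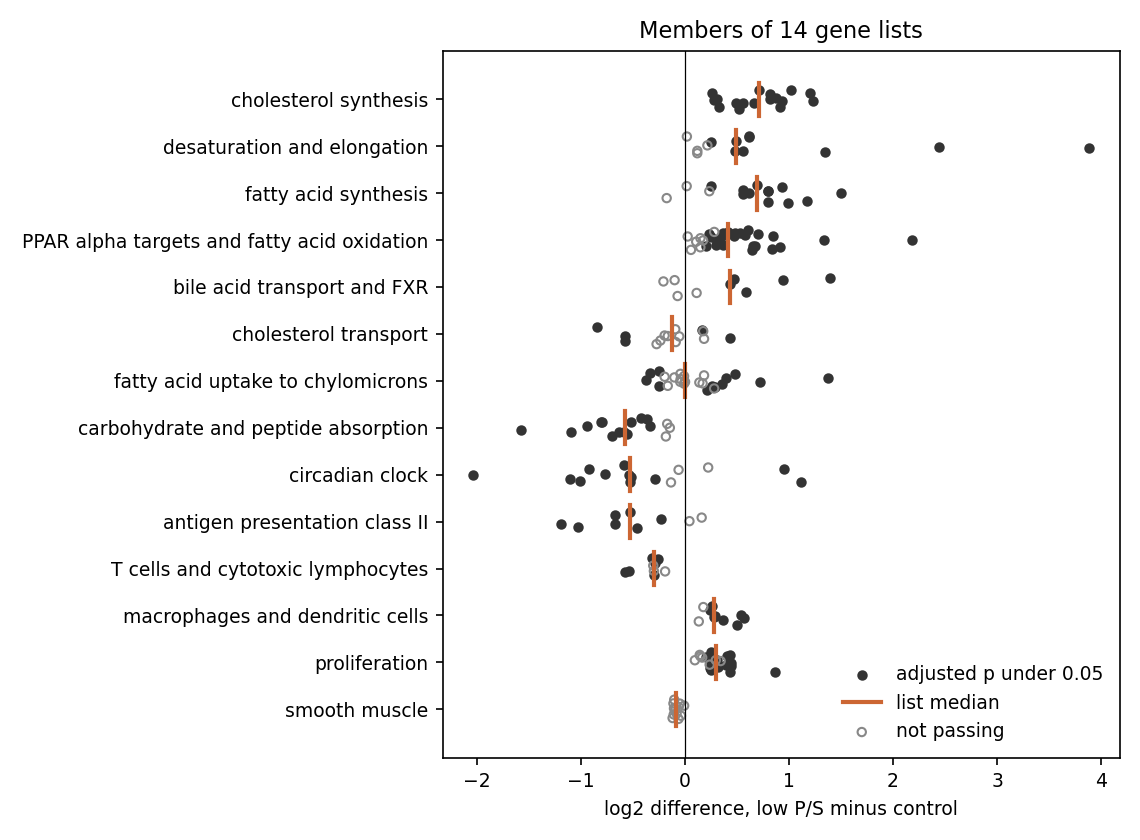
Log2 difference (low P/S minus control) of each tested member of 14 of the 38 gene lists, which were chosen after their values were seen; filled points passed at an adjusted p under 0.05, open points did not, and bars mark list medians. The medians run from 0.71 for cholesterol synthesis to -0.57 for carbohydrate and peptide digestion and absorption, and the 12 smooth muscle genes lie between -0.12 and -0.01.

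Genes of carbohydrate and peptide digestion and absorption fell in 13 of 16 cases, and 3 did not pass. Adjusted over the list alone, 14 fell. Besides Slc15a1, the brush border peptidase genes Dpp4 and Enpep were 1.63-fold and 1.5-fold lower and the neutral amino acid transporter gene Slc6a19 1.48-fold lower, each with every low P/S array below every control array. The list had the smallest camera p of all (adjusted p = 3.37e-15; adjusted p = 0.247 with an estimated correlation), and its mean fell by 0.62 on the log2 scale (exact 95% interval -0.77 to -0.45, exact permutation p = 0.0022).

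Bile acid transport and farnesoid X receptor genes were higher in 5 of 9 cases, and 4 did not pass. Adjusted over the list alone, 5 rose and 1 fell. Nr0b2, a repressor induced through the bile acid receptor, rose 2.64-fold, the basolateral bile acid exporter gene Slc51b 1.92-fold, the exporter gene Abcc3 1.38-fold and the receptor gene Nr1h4 itself 1.35-fold. The list did not pass camera (adjusted p = 0.0867), but did with quantile normalization (adjusted p = 0.0489) and with no filter (adjusted p = 0.0411), and fry gave an adjusted p of 0.00104.

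Markers of the proximal small intestine were higher in 6 of 11 cases and lower in 1, with 4 not passing and the same counts adjusted over the list alone. The junction gene Cldn2 rose 1.71-fold, the calcium-binding protein gene S100g 1.38-fold and the hormone gene Sct 1.24-fold, while the lactase gene Lct was 1.93-fold lower. Of 10 distal markers 3 rose, 1 fell and 6 did not pass, and adjusted over the list alone 3 rose and 2 fell. The bile acid uptake gene Slc10a2 rose 1.5-fold, though not with an ordinary variance per gene (adjusted p = 0.0539), and Cubn was the distal marker that fell. Neither list passed camera (adjusted p = 0.0916 for proximal and 0.870 for distal markers). The proximal list passed fry (adjusted p = 0.000816), had a mean difference of 0.15 (exact 95% interval 0.09 to 0.21, exact permutation p = 0.0022) and passed camera without low P/S array 4 (adjusted p = 0.0465).

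In retinoid and xenobiotic metabolism 7 of 20 genes fell, 2 rose and 11 did not pass, and adjusted over the list alone 8 fell and 2 rose. The cytochrome P450 genes Cyp2b10 and Cyp4f14 were 1.63-fold and 1.60-fold lower and the glucuronosyltransferase gene Ugt2b34 1.25-fold lower, whereas the efflux transporter gene Abcg2 rose 1.40-fold. The list passed camera (adjusted p = 0.00343; adjusted p = 0.364 with an estimated correlation) but not fry (adjusted p = 0.0546).

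Circadian clock genes changed in 12 of 15 cases, 10 lower and 2 higher, with 3 not passing. Adjusted over the list alone, 10 were lower and 3 higher. The output genes Dbp and Tef were 4.10-fold and 2.01-fold lower, and Cry2 and Nr1d1, which repress the clock, were 1.45-fold and 1.44-fold lower. The higher genes, which were chosen after their values were seen, were Arntl, an activator of the clock (1.11 ± 0.23), and Nfil3, a repressor of the targets of Dbp (0.95 ± 0.17). The list passed camera (adjusted p = 2.51e-05; adjusted p = 0.255 with an estimated correlation). The labels give no time of day for the dissections. A clock score correlated between arrays of the same number in the 2 diets, the strongest such match of 38 scores compared after seeing the data (r = 0.997). Its exact permutation p of 0.00139 was the smallest that 6 numbers can give. Adjusted over 38 scores it became 0.0528, so a single score could not pass whatever its r, and the adjustment cannot decide.

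**Figure D4:**
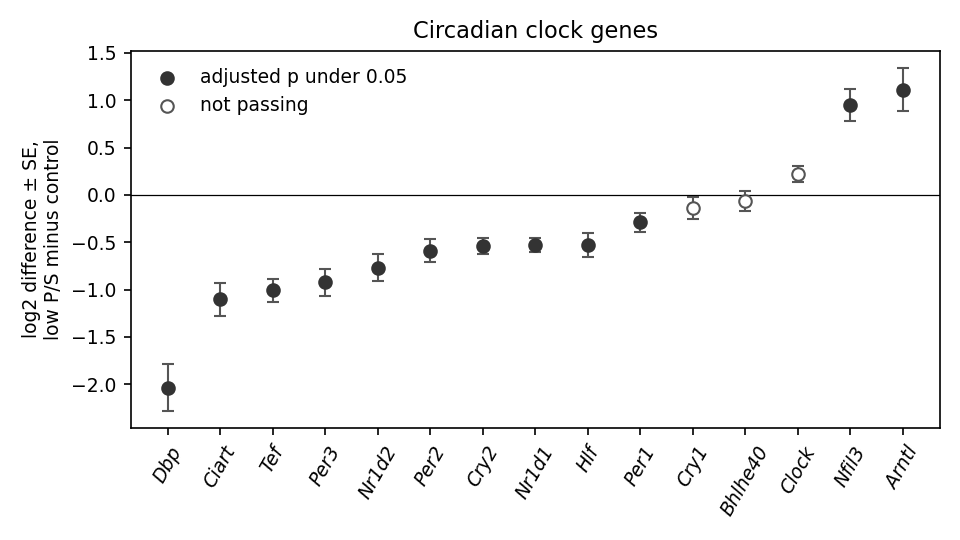
Log2 difference (low P/S minus control) ± SE of the 15 tested circadian clock genes over 6 arrays per diet; filled points passed at an adjusted p under 0.05. Values run from -2.04 for Dbp to 1.11 for Arntl.

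Class II antigen presentation genes fell in 7 of 9 cases, over all genes and adjusted over the list alone, and 2 did not pass. The class II chain genes H2-Ab1 and H2-Eb1 were 2.05-fold and 1.59-fold lower, the peptide loading gene H2-DMa 1.60-fold lower and the protease gene Ctss 1.37-fold lower. The list passed camera (adjusted p = 2.51e-05; adjusted p = 0.316 with an estimated correlation), and its mean fell by 0.51 on the log2 scale (exact 95% interval -0.75 to -0.24, exact permutation p = 0.00866). Of 14 interferon response genes 1 fell, the RNA sensor gene Ddx58 (1.11-fold lower, adjusted p = 0.0464), and 13 did not pass. No member passed adjusted over the list alone, 3 had an unadjusted limma p under 0.05, the Ddx58 call ended without any 1 of 11 of the arrays (highest adjusted p = 0.0917), and the list did not pass camera (adjusted p = 0.324).

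Markers of immune cells moved apart. T cell and cytotoxic lymphocyte genes fell in 6 of 9 cases, or 9 adjusted over the list alone, with the granzyme genes Gzma and Gzmb 1.49-fold and 1.45-fold lower and the T cell receptor component gene Cd3e 1.20-fold lower (camera adjusted p = 1.43e-05; adjusted p = 0.316 with an estimated correlation). Among members too dim to test, Cd4 and Cd2 had higher intensities on the low P/S diet (84.5 against 74.5 and 69.2 against 61.7). Cd3d, Cd8b1 and Zap70 had lower ones (61.4 against 63.8, 81.3 against 82.9 and 75.8 against 80.6). Macrophage and dendritic cell genes rose in 8 of 10 cases, or 9 adjusted over the list alone, with the complement genes C1qc and C1qb 1.48-fold and 1.41-fold higher and the growth factor receptor gene Csf1r 1.45-fold higher (camera adjusted p = 2.82e-05; adjusted p = 0.316 with an estimated correlation).

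B and plasma cell genes rose in 3 of 6 cases, or 4 adjusted over the list alone, with the antibody joining chain gene Jchain 1.73-fold and the heavy chain gene Ighm 1.35-fold higher (camera adjusted p = 0.0199; adjusted p = 0.325 with an estimated correlation). This list call ended without low P/S array 3 (adjusted p = 0.0650) and without control arrays 1 and 2 together (adjusted p = 0.0884), Ighm did not pass with an ordinary variance per gene (adjusted p = 0.0564), and the third call, Mzb1, ended without any 1 of 9 of the arrays (highest adjusted p = 0.0990). Of 7 inflammation and acute phase genes none passed, over all genes or adjusted over the list alone, and 1 had an unadjusted limma p under 0.05 (camera adjusted p = 0.621). Cxcl1, a chemokine gene, had a difference of -0.04 ± 0.06.

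Proliferation genes rose in 16 of 23 cases, or 20 adjusted over the list alone, with a median of 0.30. The replication licensing genes Mcm2 and Mcm7 rose 1.82-fold and 1.24-fold, and the mitotic kinase genes Bub1 and Plk1 1.36-fold and 1.19-fold (camera adjusted p = 3.59e-06; adjusted p = 0.364 with an estimated correlation). Of 11 crypt stem cell genes none passed, over all genes or adjusted over the list alone, and none had an unadjusted limma p under 0.05 (camera adjusted p = 0.760). The stem cell receptor gene Lgr5 had a difference of -0.14 ± 0.07.

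Genes of the unfolded protein response rose in 11 of 19 cases and fell in 1, with the same counts adjusted over the list alone. The asparagine synthetase gene Asns rose 1.65-fold, and the protein folding genes Pdia6 and Hsp90b1 1.48-fold and 1.28-fold, while Herpud1 was 1.31-fold lower (camera adjusted p = 0.000957; adjusted p = 0.347 with an estimated correlation). Respiratory chain genes rose in 13 of 21 cases, or 17 adjusted over the list alone, by a median of 0.18, with Uqcrfs1 and Ndufs3 each 1.21-fold higher (camera adjusted p = 3.29e-05; adjusted p = 0.347 with an estimated correlation). With quantile normalization 9 of these rose, by a median of 0.11, and the counts for the unfolded protein response were 9 higher and 1 lower. Of 13 genes of the oxidative stress response 3 rose, 2 fell and 8 did not pass, or 5 and 2 adjusted over the list alone (camera adjusted p = 0.229), and this list passed with no filter (adjusted p = 0.0167). The glutathione peroxidase gene Gpx2 rose 1.31-fold and Gclm, of glutathione synthesis, was 1.40-fold lower. The other fall, Gclc, did not pass without control array 5 or 6 or low P/S array 3 or 6 (highest adjusted p = 0.0675), with median centring (adjusted p = 0.0650), with array weights (adjusted p = 0.0539) or with an ordinary variance per gene (adjusted p = 0.0755).

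Goblet cell genes passed in 3 of 11 cases, with the mucin folding gene Agr2 1.55-fold higher, Clca1 1.28-fold higher and Guca2a 1.31-fold lower, and adjusted over the list alone 5 rose and 1 fell (camera adjusted p = 0.281). The Clca1 call ended without control array 4 or low P/S array 1, 2, 3 or 4 (highest adjusted p = 0.0782). Enteroendocrine genes rose in 4 of 13 cases, over all genes and adjusted over the list alone, with the hormone genes Cck 1.35-fold and Sct 1.24-fold higher (camera adjusted p = 0.133). The other 2 calls, Chgb and Pyy, ended without any 1 of 6 and of 7 arrays (highest adjusted p = 0.0795 and 0.0844), and the list passed with no filter (adjusted p = 0.0397) and by fry (adjusted p = 0.0460). Of 11 Paneth cell and antimicrobial genes 2 passed, as higher, or 3 adjusted over the list alone, none passed with quantile normalization, and the list did not pass camera (adjusted p = 0.307). The 2 calls, Pla2g2a and Reg3a, ended without any 1 of 7 and of 10 arrays (highest adjusted p = 0.107 for each), and both ended without control array 4. Of 4 tuft cell genes bright enough to test none passed, over all genes or adjusted over the list alone, and 1 had an unadjusted limma p under 0.05.

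Fibroblast and matrix genes rose in 8 of 12 cases, or 9 adjusted over the list alone, with the growth factor receptor genes Pdgfra and Pdgfrb 1.35-fold and 1.25-fold higher and the matrix gene Sparc 1.25-fold higher (camera adjusted p = 0.00130; adjusted p = 0.325 with an estimated correlation), and 6 rose with quantile normalization. Endothelial genes rose in 3 of 9 cases, or 5 adjusted over the list alone, with Emcn 1.16-fold higher (camera adjusted p = 0.0955). The other 2 calls ended without any 1 of several arrays, 6 for Kdr (highest adjusted p = 0.0777) and 4 for Lyve1 (highest adjusted p = 0.0603), while the list passed with quantile normalization (adjusted p = 0.0217), with no filter (adjusted p = 0.0170), by fry (adjusted p = 0.0141) and without low P/S array 5 (adjusted p = 0.0498). Enteric neuron and glia genes fell in 1 of 6 cases, over all genes and adjusted over the list alone, namely the neurofilament gene Prph (1.14-fold lower), whose call ended without control array 3, 4 or 6 or low P/S array 1 or 2 (highest adjusted p = 0.0683). That list passed camera as lower (adjusted p = 0.0199; adjusted p = 0.325 with an estimated correlation), but not with quantile normalization (adjusted p = 0.104).

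Of 12 smooth muscle genes none passed, over all genes or adjusted over the list alone, and none had an unadjusted limma p under 0.05 (camera adjusted p = 0.0916). The list passed as lower with quantile normalization (mean -0.15, adjusted p = 0.0382), with array weights (adjusted p = 0.0424), without control array 1 (adjusted p = 0.0463) and without low P/S array 4 (adjusted p = 0.0465). Of 6 adipose genes 1 passed, the lipase gene Lipe (1.14-fold lower), or 3 as lower adjusted over the list alone (camera adjusted p = 0.0867). The Lipe call ended without any 1 of 8 of the arrays (highest adjusted p = 0.0922), whereas the adipose list passed as lower without control array 1 (mean -0.38, adjusted p = 0.00744) or low P/S array 1 (-0.37, adjusted p = 0.0292). Of 7 exocrine pancreas genes none passed, over all genes or adjusted over the list alone, and 3 had an unadjusted limma p under 0.05 (camera adjusted p = 0.324). Of 15 immediate early genes 1 passed, Klf4 (1.16-fold lower), or none adjusted over the list alone (camera adjusted p = 0.0955), against 4 lower with quantile normalization and 0 with median centring, and the Klf4 call ended without any 1 of 8 of the arrays (highest adjusted p = 0.0830). This list passed camera as lower without low P/S array 4 (mean -0.20, adjusted p = 0.000692), without control array 3 (adjusted p = 0.0275) and with the 60th percentile filter (adjusted p = 0.0318). The mast cell list and the erythrocyte list each had 1 gene bright enough to test, Kit with a difference of -0.03 and Slc4a1 with -0.09, and neither passed, over all genes or adjusted over the list alone.

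Of the 35 lists tested with camera at a preset correlation, 17 passed, 10 as higher and 7 as lower. With an estimated correlation none passed, 5 had an unadjusted p under 0.05, and fry called 21. The median, the mean and the camera direction differed in sign for the lists of sterol sensing, of fatty acid uptake and chylomicrons, of inflammation and of crypt stem cells, none of which passed.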

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

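Chosen only after the result was seen were the tests of single arrays and of the time of dissection for the clock genes, of the enterocyte share and the segment for the digestion genes, of macrophages and the interferon response for the class II genes, the ranking of lists by their relation to the clock score, and the match of scores between arrays of the same number. The counts of splits and both relations within diets were chosen before.

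Of 100 splits of the 12 arrays, 1, the real one, called as many genes, with 3074 genes against at most 1855 in the other splits. Chance alone was therefore unlikely for the gene count, to the limit of 1 in 100 that the draw allows. Such splits cannot separate the diet from handling, feeding or batches shared by a group. For the count of lists, 11 of 100 splits called as many (17 lists in the real split, at most 20 in the others). The split with 20 lists put 4 low P/S arrays beside control array 1, so it still kept the diets partly apart. Among splits with 3 low P/S arrays there, the most was 14 lists. The count therefore mixes chance with part of the diet difference, and chance could not be excluded for the number of lists called at the preset correlation.

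The circadian clock genes differed between the diets in a clock score. Its opposite-phase genes were the tested ones among Arntl, Npas2, Clock, Nfil3 and Cry1. The score was the mean of all other tested clock genes, not only output genes, minus the mean of the opposite-phase genes. It fell by 1.30 on the log2 scale (exact 95% interval -1.83 to -0.72, exact permutation p = 0.0022). A few arrays do not account for it, since the lowest control score lay 0.12 above the highest low P/S score. In 14 of 15 tested clock genes the direction followed this grouping, with the opposite-phase genes higher and the rest lower. The grouping was applied after the result was seen, so the count cannot decide whether the phase shifted. Scores of arrays with the same number correlated between diets (r = 0.997 over 6 numbers, exact permutation p = 0.00139, adjusted 0.0528 over 38 scores, Spearman rho = 1, exact p = 0.00278, r = 0.996 without the 2 farthest numbers). The exact permutation p was the smallest that 6 numbers can give, so a single score could not pass the adjustment. The scores differed by -1.48 to -1.08 within a number, so an order of handling shared by both diets may lie behind the spread within diets. A difference in the time of dissection or of the last feeding cannot be told apart from a response of the clock to the diet, since the labels give no times, and an effect of the diet on the clock stays open as a hypothesis.

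For the digestion and absorption genes, lower on the low P/S diet, a lower share of absorptive enterocytes was taken to raise markers of other cells alike. The macrophage minus T cell contrast differed by 0.67 (exact 95% interval 0.53 to 0.83, exact permutation p = 0.0022) and the T cell list fell. This contrast cannot decide the question, since T cells lying within the epithelium could fall along with enterocytes. The macrophage, B and plasma cell, fibroblast and endothelium lists differed by 0.33, 0.33, 0.21 and 0.13. Those of T cells, enteric neurons and glia, smooth muscle and adipose tissue differed by -0.34, -0.12, -0.08 and -0.27. Lists of other absorptive functions were mixed. Fatty acid uptake to chylomicrons differed by 0.12 (exact 95% interval -0.03 to 0.27). Cholesterol transport differed by -0.16 (-0.26 to -0.05) and retinoid and xenobiotic metabolism by -0.15 (-0.28 to -0.02). The fall of the digestion genes was thus not shared by all absorptive lists. Those lists may respond to the diet themselves, so a lower share of enterocytes was not excluded. Sampling of another segment cannot be told apart, since the distal minus proximal contrast differed by -0.14 with an exact 95% interval of -0.32 to 0.03, which reached beyond the bound of 0.31 set by 50% of the fall. The clock phase of each animal may contribute, since within diets arrays with a lower clock score had a lower digestion score (pooled r = 0.73, permutation p = 0.0130, adjusted 0.0260 over 2 relations, Spearman rho = 0.66, permutation p = 0.0326). That r was 0.87 among control and 0.65 among low P/S arrays, and 0.56 over the 10 arrays left without control array 6 and low P/S array 6, where it no longer passed (permutation p = 0.106). Clock scores correlated by number, so an order of handling was not separated from the clock as a source of this relation. The relation was not specific either, as the interferon list had a larger r of -0.76 among 34 lists and the fatty acid oxidation list one of -0.71. For the lists of fatty acid synthesis and cholesterol synthesis r was -0.63 and -0.57.

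The class II antigen presentation genes were lower on the low P/S diet. Fewer macrophages would lower their markers, but the macrophage and dendritic cell list rose by 0.33 (exact 95% interval 0.19 to 0.47, exact permutation p = 0.0022). Most genes of that list mark macrophages, so it cannot decide whether dendritic cells were fewer. A weaker interferon response throughout the tissue was bounded by the interferon list, whose difference of -0.0192 had an exact 95% interval of -0.16 to 0.11, against the fall of 0.25 that 50% of the class II change would need. This bound holds for the mean of the 14 tested genes, as other members such as Mx1 and Oas2 were too dim to test. The list does not separate the types of interferon, so a weaker signal of a single type was not excluded. Whether fewer T cells in the same animals go with it cannot be told apart, since the relation within diets was too weak for 12 arrays to decide (pooled r = 0.27, permutation p = 0.404, adjusted 0.404, Spearman rho = 0.49, permutation p = 0.126, r = 0.26 without low P/S arrays 4 and 5). A response of class II expression to the diet stays open, untested.

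Single arrays stood apart from the other 5 of their group for 13 of 320 tests of a gene in a diet, by the gap to the nearest array over the group's range, and chance gives about 1 in 20 such groups. Control array 2 did so in 5 cases. It was highest for H2-Q10 (gap 0.732 of the range, intensity 302 against a median of 198 in the others) and lowest for Npc1l1 (0.640, 2106 against 2973), Abcg5 (0.694, 2121 against 2743), Il18 (0.778, 437 against 513) and Sox10 (0.742, 90.9 against 103). Control array 5 was highest for H2-Ab1 (0.641, 1290 against 739), and control array 6 was lowest for Clca1 (0.656, 2250 against 3561). Low P/S array 3 was highest for H2-DMa (0.675, 160 against 113) and Mzb1 (0.688, 153 against 116). Low P/S array 4 was highest for Emcn (0.667, 121 against 94.7), and low P/S array 5 was lowest for Cd8a (0.770, 146 against 188). Low P/S array 6 was lowest for Tpm2 (0.668, 363 against 446) and Myl9 (0.781, 754 against 1205).

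Probe sets outside the gene comparison also differed. Of 701 tested probe sets naming several genes, 85 were higher and 20 lower on the low P/S diet, and of 5368 naming no gene, 171 were higher and 71 lower.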

How the results depend on the processing

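The pseudocount of 1, the subtraction of 16, the fit without control arrays 1 and 2 together and the liver X receptor list without Scd1 and Scd2 were chosen after seeing the data. The count of differing genes was 3074 and ranged from 2457 with an ordinary variance per gene to 3852 without control arrays 1 and 2, and with single arrays left out from 2410 (without low P/S array 4) to 3321 (without control array 2). Quantile normalization gave 1543 lower genes in place of 942, shared 2627 calls with the reported fit, and moved the share of higher genes from 69.4% to 53.5%. With the replicate number as a replicate block 3530 genes and 17 lists passed. The choice not to treat the numbers as pairs was fixed before the data were examined. Deviations from the group means correlated between arrays of the same number at -0.109 to 0.418, and 2 of 6 arrays had their own number as best partner. The clock score correlated by number (r = 0.997), and 7 of 38 scores had an unadjusted exact p under 0.05. None passed after adjustment, which a single score over 6 numbers could not do. An effect shared by arrays of the same number was therefore not excluded. With an estimated correlation, the lists passing fell from 17 to 0, the higher from 10 to 0 and the lower from 7 to 0, since camera then widens the variance of each list. Otherwise 14 of 17 passing lists kept their call in every other setting in which they were tested, and 15 in every leave-one-out fit. Of 118 passing named genes, 101 kept direction and call in every setting in which they were tested. In every leave-one-out fit 104 did so, and none reversed in any fit. With the stricter filter on dim genes, 125 of 160 named genes kept their result and 4 gained a call. The other named genes were not tested with that filter, nor were some lists, so their stability there is unknown. Of 18 lists that did not pass, 9 gained a call in some other setting and 5 in a leave-one-out fit, and of 42 such named genes 19 and 21.

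Reversals touched only results that did not pass. The Cd36 difference was 0.0159 with median centring, 0.00947 with array weights and 0.0220 without control arrays 1 and 2, and Gfi1b was -0.0446 in that last fit. List means, whose camera direction turned, were 0.0338 with median centring and -0.0502 with the 60th percentile filter for distal markers, 0.00840 with no filter and 0.0103 by fry for crypt stem cells, 0.0783 in both for sterol sensing, and 0.121 with the 60th percentile filter for fatty acid uptake. Leaving out single arrays gave -0.0512 to 0.0174 for Cd36, -0.0743 to 0.000218 for Cxcl1, -0.0597 to 0.000386 for Kit, -0.0843 to 0.272 for Ptgs2, -0.0130 to 0.0360 for crypt stem cells, -0.0313 to 0.0564 for distal markers and 0.0796 to 0.145 for fatty acid uptake. For the reversals and for quantile normalization the cause was not tested. Dim genes near the floor of 85.6 and differences near the median standard error of 0.061 set the limit of what these arrays resolve.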

Other observations

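The gene families below were chosen after seeing the data. Of 47 proteasome subunit genes 35 rose and 1 fell (median 0.32, camera adjusted p = 3.95e-11; adjusted p = 0.162 with an estimated correlation). The gene that fell was Psmb8, a subunit of the immunoproteasome (-0.37), whereas Psmb3 and Psmd4 rose by 0.56 and 0.53. Of 76 mitochondrial ribosomal protein genes 55 rose (median 0.25; adjusted p = 0.162 with an estimated correlation), and of 54 cytosolic ribosomal protein genes 35 rose (median 0.20; adjusted p = 0.162 with an estimated correlation). With quantile normalization these counts were 32 higher and 3 lower for the proteasome, 48 for mitochondrial and 25 for cytosolic ribosomal proteins. Of 18 cytosolic aminoacyl-tRNA synthetase genes 14 rose, led by Nars (0.66), and of 10 genes of the translocon and signal peptidase 8 rose (each adjusted p = 0.162 with an estimated correlation).

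Of 245 solute carrier genes 49 rose and 55 fell (median -0.00918, camera adjusted p = 0.00936; adjusted p = 0.246 with an estimated correlation), or 41 and 63 with quantile normalization. Beyond the sugar and peptide carriers, those that fell included the nucleoside transporter gene Slc28a2 (-1.24) and the amino acid transporter genes Slc43a2 (-1.12) and Slc7a8 (-0.88), and those that rose included the phosphate transporter gene Slc34a2 (0.93) and the sodium-hydrogen exchanger gene Slc9a3 (0.78). Of 35 cytochrome P450 genes 15 fell and 4 rose (camera adjusted p = 8.75e-05; adjusted p = 0.0817 with an estimated correlation), with Cyp27a1, a sterol hydroxylase, lowest at -1.29. Of 6 glucuronosyltransferase genes 2 fell (adjusted p = 0.162 with an estimated correlation), or 4 with quantile normalization, and of 13 peroxisome biogenesis genes 5 rose (adjusted p = 0.246 with an estimated correlation), or 3 with quantile normalization. Aquaporins passed in 4 of 8 cases, 3 higher and 1 lower, with Aqp1 lower (-1.08) and Aqp3 higher (0.42), and the family did not pass camera (adjusted p = 0.662). Class I histocompatibility genes passed in 4 of 8 cases, 2 higher and 2 lower, or 2 and 4 with quantile normalization, and did not pass camera as a family (adjusted p = 0.662).

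Of 6 immunoglobulin segment genes 4 rose (median 0.74; adjusted p = 0.0817 with an estimated correlation). Among the probe sets naming several genes, those shared by Igha and immunoglobulin variable segments were up to 1.18 higher, and a probe set shared by Sprr2a and Sprr2b genes of the cornified envelope family was 1.41 higher. A probe set shared by Apol9a and Apol9b was lower (-0.85).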
